A study of Oncorhynchus mykiss with 39 samples.

How the data were processed

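Total RNA from 39 livers was labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels' protocols. Groups, tanks and fish were taken from the sample titles, which name 5 groups of 3 tanks each (15 tanks). The labels describe the 7.1 mg/kg group with 8 livers in a list that sums to 40, while the titles give 7 such fish among 39 arrays, and any further liver is not analysed here. Fish are separate animals, but the tank is the unit that was dosed. The selenium content of the control diet is not given in the sources used here.

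The deposited scanner tables hold intensity values per spot on a linear scale, made with Agilent Feature Extraction 10.7.1.1 per the file headers and 10.7 per the submitters' processing notes. The processed signal used here is background-subtracted by that software, and the tables also give a median signal, a local background median and flags for spots well above background, saturated or outlying. The deposited value table of the authors holds log2 values of the same arrays, with array medians from 5.65 to 5.77 and a floor at 2.75 that 13.7 to 17.4% of the spots of an array share. Its columns had Spearman correlations of 0.9865 to 0.9987 with the scanner signal. Its scale is close between arrays, but the scaling and flooring method are not given in the sources used here.

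Each array held 44925 spots, of which 43508 were not control spots and made up 21754 probes in 2 spots each. Control spots were left out, spots with a non-uniformity or population outlier flag were set to missing (1 to 926 spots per array, 292 missing probe values in all), saturated spots (0 to 3 per array) were kept, and the spots of a probe were averaged. Values were log2 of the processed signal minus the array's 75th percentile, which lay between 6.81 and 8.73 (median 8.26) and sets aside differences in overall brightness. A global shift in RNA content would be removed with it. A probe was tested if it was well above background on at least 7 arrays, which kept 19866 probes and left out 1888. Array background medians ranged from 20.5 to 46.0. The highest correlation of 2 arrays was 0.985 and the lowest 0.933, and 0 pairs were identical, so each array counted as 1 sample. The median correlation was 0.968 within groups and 0.966 between them.

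Groups were compared with limma 3.58.1 and statmod 1.5.0 in R 4.3.3 (package data.table, version 1.17.8), with a mean per group over all 39 arrays, tank as a random block (estimated correlation 0.0066) and two-sided moderated tests. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. The dose trend used steps from 0 to 4 in place of group means. The test, the filter, the dose comparisons with control, the comparison of 31.8 with 7.1 mg/kg, the trend, the F test, the overlap and most alternatives were fixed before the data were examined. The comparisons of neighbouring doses, the position score and its tests, and the alternatives with scan date as a block, array quality as a covariate, single fish left out and a pair of fish left out were added later, as was the change on each slide or scan date of probes called without its arrays. Fold differences are given on the scaled log2 signal. Where a probe was not well above background on any array of a group, the fold is given as a lower bound on this scale. It was taken from the bright group's mean and, per dim array, the higher of the probe's own signal and the lowest signal well above background. That lowest signal may come from any probe, so it is not the detection limit of the probe itself.

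The systematic names in the files matched 0 of 72772 genes in the gene name list of assembly USDA_OmykA_1.1, and the files hold no gene names. Probe names matched 0 as well. The gene lists and the marker lists fixed beforehand, with their set tests, therefore have no result. The rule for named genes (the 12 largest rises and the 12 largest falls at 31.8 mg/kg, and smaller sets elsewhere, among called probes with all 3 tanks on one side) was reduced to the 2 largest rises and the 2 largest falls, because probes without a gene name are given by identifier.

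Arrays lay on 10 slides, with no more than 1 array of a group on a slide, and were scanned on 3 dates. Arrays on scan dates 1, 2 and 3 numbered 2, 3 and 3 for control, 2, 2 and 3 for 7.1 mg/kg, 1, 3 and 3 for 10.7 mg/kg, 1, 3 and 4 for 19.5 mg/kg and 2, 4 and 3 for 31.8 mg/kg. Slide and scan date were therefore fitted as blocks, and values were also taken within them. The alternatives fixed beforehand were slide and tank letter as blocks, no tank block, tank means, other scalings (median, quantile, normexp with offset 50 and quantile), the authors' value table, other filters, outlier spots kept, a robust fit with an intensity trend, the arrays of 2 groups alone, the trend over log2 mg/kg, and each tank left out. The tables give no mean signal, so normexp used the median signal and the background median.

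The fit was tested on simulated data with each probe's own mean and spread. Errors were drawn independently for each probe, so any correlation between probes of the real arrays was absent. The false calls given next therefore do not measure the error rate on the real arrays. For 31.8 mg/kg against control, in a step on 19629 probes, it recovered 51 of 100 probes changed by 1 log2 unit and 92 of 100 changed by 2 log2 units, with 13 false calls among 156. Shared controls were treated by simulating unchanged groups 100 times and by splitting the controls. In each simulation whole residual arrays were redrawn for every group, controls included. All doses were then set against those controls, in a fit without the tank block. Single measures were compared with two-sided exact permutation tests. Plots were drawn with matplotlib 3.10.9.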

Results

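Gene expression was measured in the livers of 39 juvenile rainbow trout (Oncorhynchus mykiss) with one-colour Agilent arrays, after the fish had received organic selenium in the diet for 60 days. Control fish (n = 8) were compared with fish dosed at 7.1 mg/kg (n = 7), 10.7 mg/kg (n = 7), 19.5 mg/kg (n = 8) and 31.8 mg/kg (n = 9). The fish of each group came from 3 tanks. Each array carried 21754 probes in 2 spots each, and 19866 probes were tested. The percent of probes well above background ranged from 57.5 to 94.1 (median 83.6) over the arrays, and its group mean was 81.0 ± 5.82 (SD, n = 8) in controls, 81.9 ± 11.7 (n = 7) at 7.1 mg/kg, 82.0 ± 4.40 (n = 7) at 10.7 mg/kg, 84.4 ± 2.76 (n = 8) at 19.5 mg/kg and 84.3 ± 3.32 (n = 9) at 31.8 mg/kg. The number of arrays limits the precision of every comparison. The files pair no probe with a gene name, so probes are given by their identifiers and no pathway was tested. The probes named are the pair with the largest rise and the pair with the largest fall at 31.8 mg/kg among called probes that moved the same way in all 3 tanks.

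The first question was which transcripts differed from control at the highest dose. At 31.8 mg/kg, 163 probes were higher and 111 were lower than in control livers. Of these 274 probes, 157 differed by more than 2-fold, 87 upward and 70 downward, and the median size of change was 1.1 on the log2 scale. On this scale the largest rise was that of CUST_6482_PI425320672, from a scaled log2 signal of -5.64 ± 1.94 (SD, n = 8) in controls to 0.96 ± 1.75 (n = 9). The largest fall on this scale was that of CUST_14405_PI425320672, from 0.03 ± 0.79 (n = 8) to -5.52 ± 2.09 (n = 9), where 3 of 9 arrays measured it well above background, and with normexp and quantile normalization its change of -1.31 was smaller than the -2.51 of CUST_995_PI425320422. The calls are from limma at an adjusted p under 0.05. All 3 dosed tanks lay on one side of the control mean for each of the 274 probes, which a call on the same arrays makes likely and which is no separate check. At an unadjusted p under 0.05 there were 2186 probes, against 993 expected by chance. When each of the 3 scan dates was fitted alone, 11, 20 and 0 probes passed, with 1204 at an unadjusted p under 0.05 in limma on the third. Of probes called without the arrays of a date (20, 2 and 177), the median change on that date, in the direction of the call, was 1.64, 3.59 and 0.80. Of probes called without the arrays of a slide (80 to 253), it was positive on 7 of 7 slides, from 0.61 to 1.62, and 199 probes were called with slide as a block. The count was 60 on tank means, 141 with median scaling and 180 with scan date as a block. On tank means 28 were higher and 32 lower, so the larger number of rises did not hold there. It was 127, 140 and 137 without control Tank A, B and C, 113 and 100 without the 31.8 mg/kg Tank A and Tank B, and 175 without the 31.8 mg/kg fish Tank A Fish 2.

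CUST_6482_PI425320672 was 6.60 log2 units higher at 31.8 mg/kg than in controls (SE 1.04, adjusted p = 0.000309 in limma). Only 1 of 8 control arrays, that of Tank B Fish 3 at -1.05, measured it well above background, against 9 of 9 dosed arrays, so the size of the difference rests on a control level at background, and it was 7.26 without that fish. CUST_2920_PI425320672 was 6.05 log2 units higher (SE 1.06, adjusted p = 0.00124), from -6.03 ± 1.84 (n = 8) to 0.02 ± 2.17 (n = 9), and was likewise well above background on that 1 of 8 control arrays, at -1.58. CUST_14405_PI425320672 changed by -5.56 log2 units (SE 0.78, adjusted p = 0.000105), and 3 of 9 dosed arrays measured it well above background against 8 of 8 control arrays. CUST_995_PI425320422 changed by -4.54 log2 units (SE 0.82, adjusted p = 0.00153), from 2.69 ± 1.32 (n = 8) to -1.85 ± 2.00 (n = 9), and was measured on every array. For each of the 4 probes, 9 of 9 dosed fish lay beyond the control mean in the direction of the call, and the difference had the same sign on 7 of 7 slides that held both groups, for probes that were chosen on these arrays. On the 3 scan dates the differences were 7.61, 8.07 and 4.21 for CUST_6482_PI425320672, 7.23, 7.78 and 3.16 for CUST_2920_PI425320672, -7.14, -6.64 and -3.07 for CUST_14405_PI425320672 and -4.59, -6.06 and -2.74 for CUST_995_PI425320422. With normexp and quantile normalization the 4 changes were smaller, at 1.98, 1.71, -1.31 and -2.51 in the order given.

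**Figure D1:**
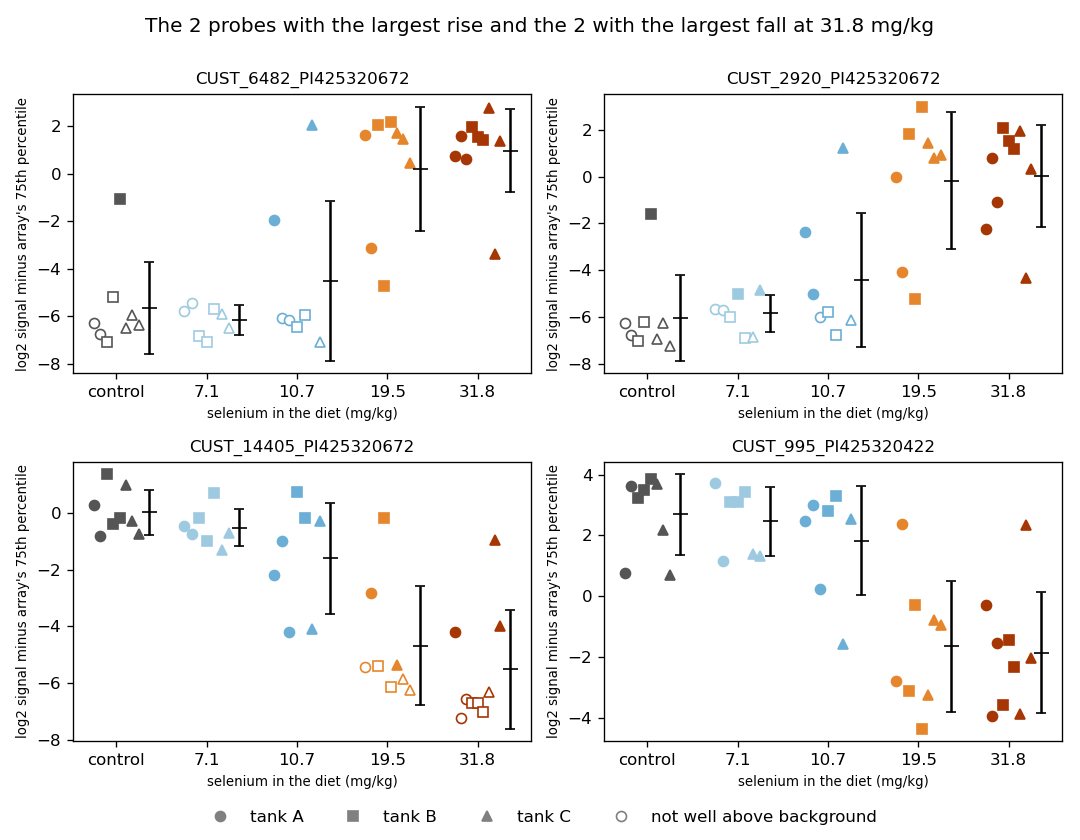
Scaled log2 signal (vertical axis) of each fish for the 4 named probes, by dietary selenium group, with group mean and SD. The rising pair lies near background in most control, 7.1 and 10.7 mg/kg fish and higher in most 19.5 and 31.8 mg/kg fish, and the falling pair shows the opposite order.

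The second highest dose was set against control in the same fit. At 19.5 mg/kg, 71 probes were higher and 133 lower than in control livers, 204 in all. Of these, 126 differed by more than 2-fold, 47 upward and 79 downward, and the median size of change was 1.13 log2 units. The 4 named probes had moved in the same directions as at 31.8 mg/kg. CUST_6482_PI425320672 was higher by 5.85 log2 units (SE 1.07, adjusted p = 0.00367 in limma) and reached 0.20 ± 2.63 (n = 8), and CUST_2920_PI425320672 was higher by 5.85 (SE 1.09, adjusted p = 0.00367). CUST_14405_PI425320672 changed by -4.71 (SE 0.81, adjusted p = 0.00174) and CUST_995_PI425320422 by -4.33 (SE 0.84, adjusted p = 0.0057), and for each of the 4 probes 8 of 8 fish lay beyond the control mean. Both rising probes were well above background on 1 of 8 control arrays and 8 of 8 dosed arrays, and CUST_14405_PI425320672 on 3 of 8 dosed arrays. The sign was the same on 6 of 6 slides that held both groups, except for CUST_995_PI425320422 with 5 of 6. On the 3 scan dates the differences were 7.57, 8.30 and 3.21 for CUST_6482_PI425320672, 7.04, 8.25 and 3.50 for CUST_2920_PI425320672, -5.88, -5.72 and -3.68 for CUST_14405_PI425320672 and -2.24, -6.86 and -3.27 for CUST_995_PI425320422. At an unadjusted p under 0.05 there were 2678 probes. The share of called probes that were higher was 34.8%, against 53.8% in the authors' value table, 49.3% with normexp and quantile normalization, 46.8% with quantile normalization alone and 46.0% with median scaling.

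Fitted alone, the 3 scan dates gave 2, 36 and 0 calls at 19.5 mg/kg against control, the last with 695 at an unadjusted p under 0.05 in limma, and the first from 1 dosed array that is assumed to vary like the other groups. Of probes called without the arrays of a date, the median change on that date, in the direction of the call, was 0.81 on the first (30 probes) and 0.79 on the third (146 probes), and without the second date 0 probes were called. Of probes called without the arrays of a slide (70 to 310), it was positive on 6 of 6 slides, from 0.23 to 1.31, and with slide as a block the count was 65. It was 46 on tank means, 100 with median scaling, 105 with the arrays of these 2 groups alone and 370 with probes required to be well above background on all 39 arrays. Without control Tank A, B and C it was 63, 40 and 310, and without the 19.5 mg/kg Tank A and Tank C it was 120 and 23. Without single control fish it was 97 (Tank B Fish 1) and 102 (Tank B Fish 2), and without single 19.5 mg/kg fish it was 81 (Tank A Fish 1), 316 (Tank B Fish 2), 135 (Tank B Fish 3) and 120 (Tank C Fish 1).

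At the lower doses no probe passed the threshold. The 7.1 mg/kg group had 0 calls in limma with 774 probes at an unadjusted p under 0.05, and the 10.7 mg/kg group had 0 with 483, against 993 expected by chance. CUST_6482_PI425320672 lay at -6.17 ± 0.62 (n = 7) at 7.1 mg/kg, where it was well above background on 0 of 7 arrays, and at -4.52 ± 3.36 (n = 7) at 10.7 mg/kg. CUST_14405_PI425320672 lay at -0.52 ± 0.65 (n = 7) and -1.60 ± 1.96 (n = 7), and CUST_995_PI425320422 at 2.46 ± 1.12 (n = 7) and 1.83 ± 1.80 (n = 7). None of the 4 named probes passed at either dose (adjusted p = 1 at 7.1 mg/kg and 0.999 at 10.7 mg/kg). The lowest adjusted p over all probes was 0.207 at 7.1 mg/kg and 0.999 at 10.7 mg/kg. Each scan date fitted alone gave 0 calls for both doses in limma, with 863, 1555 and 906 probes at an unadjusted p under 0.05 for 7.1 mg/kg and 1489, 507 and 717 for 10.7 mg/kg. With 1 to 3 arrays of a dose on a date (1 of 10.7 mg/kg on the first, assumed to vary like the other groups) these counts have little power, and 31.8 mg/kg against control gave 0 on the third date too (1204). Without the control fish Tank C Fish 2, 1 probe was called at 7.1 mg/kg.

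**Figure D2:**
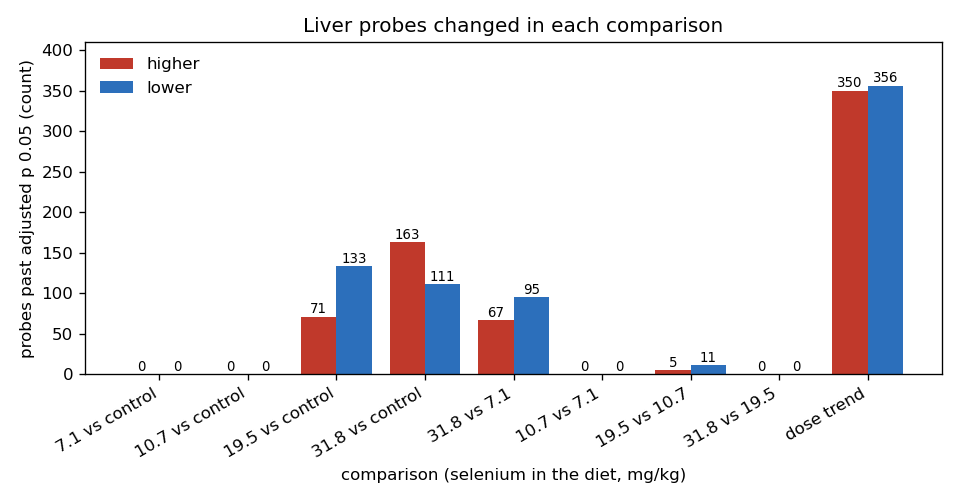
Number of probes called higher and lower (vertical axis, limma adjusted p under 0.05) for each comparison. Against control the count is 0 in limma at 7.1 and 10.7 mg/kg (774 and 483 at an unadjusted p under 0.05), 204 at 19.5 mg/kg and 274 at 31.8 mg/kg.

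The highest dose was also set against the lowest, so that control arrays enter only the shared estimate of the spread. At 31.8 mg/kg, 67 probes were higher and 95 lower than at 7.1 mg/kg, and 129 of these 162 differed by more than 2-fold, with a median size of 1.44 log2 units. CUST_6482_PI425320672 was at least 119-fold higher on this scale (adjusted p = 0.000592 in limma), the 7.1 mg/kg arrays giving only a bound. That bound depends on the processing, since the change of this probe against control was only 1.98 log2 units with normexp and quantile normalization. CUST_2920_PI425320672 was higher by 5.87 log2 units (SE 1.09, adjusted p = 0.00409), with 2 of 7 of the 7.1 mg/kg arrays well above background. CUST_14405_PI425320672 changed by -5.00 (SE 0.81, adjusted p = 0.00104) and CUST_995_PI425320422 by -4.31 (SE 0.85, adjusted p = 0.0058), and 9 of 9 fish of the higher dose lay beyond the mean of the lower for each of the 4 probes. At an unadjusted p under 0.05 there were 1700 probes. The scan dates fitted alone gave 7, 9 and 0 calls (1949 at an unadjusted p under 0.05 in limma on the third), and of the 2, 4 and 79 probes called without a date the median change on it, in the direction of the call, was 2.57, 1.88 and 1.14. Of probes called without a slide (31 to 248) it was positive on 6 of 6 slides, from 0.24 to 2.10. With slide as a block 120 probes were called, and with the arrays of these 2 groups alone also 120.

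The count for 31.8 against 7.1 mg/kg was 84 on tank means, 79 with median scaling and 97 with scan date as a block, and the share called higher was 41.4%, against 53.2% with median scaling. It was 101, 33 and 52 without the 7.1 mg/kg Tank A, B and C, and 54, 23 and 333 without the 31.8 mg/kg Tank A, B and C. Without single 7.1 mg/kg fish it was 99 (Tank A Fish 1), 73 (Tank B Fish 1), 94 (Tank B Fish 3) and 75 (Tank C Fish 1). Without single 31.8 mg/kg fish it was 92 (Tank A Fish 2), 92 (Tank B Fish 1), 86 (Tank B Fish 3), 89 (Tank C Fish 1), 299 (Tank C Fish 2) and 100 (Tank C Fish 3). Without both the 31.8 mg/kg fish Tank C Fish 2 and the 10.7 mg/kg fish Tank C Fish 1, a pair chosen for lying apart from their groups, it was 341.

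Neighbouring doses were compared as an addition made after the data had been seen. Between 10.7 and 19.5 mg/kg, 5 probes were higher and 11 lower at the higher dose, with a median size of 1.5 log2 units and 1894 probes at an unadjusted p under 0.05. None of the 4 named probes passed here, with a difference of 4.73 (SE 1.11, adjusted p = 0.0755 in limma) for CUST_6482_PI425320672 and -3.46 (SE 0.87, adjusted p = 0.109) for CUST_995_PI425320422. The comparison of 7.1 with 10.7 mg/kg gave 0 calls in limma (646 at an unadjusted p under 0.05), as did 19.5 with 31.8 mg/kg (805), where CUST_6482_PI425320672 differed by 0.75 (SE 1.04, adjusted p = 1). For 19.5 against 10.7 mg/kg the scan dates alone gave 1, 33 and 0 calls (786 at an unadjusted p under 0.05 in limma on the third), the first from 1 array against 1 with the spread taken from the other groups. Of the 94 probes called without the third date, the median change on it in the direction of the call was 0.40, and without either other date 0 were called. Probes were called without 2 of the 5 slides that held both groups (61 and 75), and their medians there were 0.48 and 0.37.

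The 16 calls between 10.7 and 19.5 mg/kg became 0 in limma on tank means (1835 at an unadjusted p under 0.05) or with slide as a block (1808), 3 with these groups' arrays alone, 8 with array quality as a covariate, 10 with scan date as a block, 27 in the authors' value table and 33 with probes well above background on all arrays. The share called higher was 31.2%, against 55.6% in the authors' value table and 45.0% with normexp and quantile normalization. Without the 10.7 mg/kg Tank A, B and C the count was 0, 0 and 48, and without the 19.5 mg/kg Tank A, B and C it was 32, 89 and 0. Without single 10.7 mg/kg fish it was 8 (Tank A Fish 2), 35 (Tank A Fish 3), 0 (Tank B Fish 2), 87 (Tank C Fish 1) and 7 (Tank C Fish 3). Without single 19.5 mg/kg fish it was 0 (Tank A Fish 1), 61 (Tank A Fish 2), 87 (Tank B Fish 2), 3 (Tank B Fish 3), 0 (Tank C Fish 1) and 10 (Tank C Fish 3). The 10.7 against 7.1 mg/kg count was 1 without the 10.7 mg/kg Tank A, and the 31.8 against 19.5 mg/kg count was 1 without the 19.5 mg/kg Tank C.

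Over the ordered doses, 350 probes rose and 356 fell with dose step, against 486 and 350 in the authors' value table, 470 and 341 with normexp and quantile normalization, 428 and 329 with quantile normalization alone and 307 and 232 with median scaling. CUST_6482_PI425320672 rose by 1.94 log2 units per step (SE 0.26, adjusted p = 7.66e-06 in limma) and CUST_2920_PI425320672 by 1.76 (SE 0.25, adjusted p = 1.73e-05), while the slope was -1.52 (SE 0.18, adjusted p = 1.78e-06) for CUST_14405_PI425320672 and -1.31 (SE 0.19, adjusted p = 3.69e-05) for CUST_995_PI425320422. The median change of the rising probes against control was 0.17, 0.19, 0.80 and 0.91 log2 units at 7.1, 10.7, 19.5 and 31.8 mg/kg, and that of the falling probes was -0.08, -0.23, -0.81 and -0.83. These probes were selected for their slope on the same arrays and all 4 values share the controls, so an increase with dose is built into them. Of the 706 trend probes, 259 were also called at 31.8 mg/kg, 170 at 19.5 mg/kg and 382 at neither, and 130 were ordered through all 4 doses. The F test over all groups called 356 probes, 294 of which were trend probes, and at an unadjusted p under 0.05 there were 3103 trend probes and 2178 by the F test. The trend count was 238 on tank means, 432 with slide as a block, 363 over the dosed fish on log2 mg/kg and 460 without the 31.8 mg/kg Tank B. The F count was 97 on tank means, 200 with slide as a block, 210 with median scaling, and 168, 213 and 229 without the 19.5 mg/kg Tank C and the 31.8 mg/kg Tank A and Tank B.

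The calls at 19.5 and 31.8 mg/kg shared 105 probes, 50 higher at both doses, 55 lower at both and 0 in opposite directions. Independent lists of these sizes would share 0.583 probes upward and 0.743 downward. Unchanged groups, simulated with one set of redrawn controls for all doses, shared at most 0 in 100 draws. Groups without effect give few calls to share, so this count of 0 says little about lists of the real sizes. With the 8 control arrays split between the comparisons, a mean of 10.5 probes was shared, the 2 sets of controls calling 36 and 26 probes at 19.5 mg/kg and 92 and 76 at 31.8 mg/kg. Across probes, which are not independent replicates, the correlation of the fold changes was 0.760, against 0.540 ± 0.184 (SD) simulated without effect and 0.336 with split controls. The covariance was 0.136, against 0.0577 ± 0.0299 simulated and 0.0794 with split controls. At 7.1 and 31.8 mg/kg the correlation was 0.329, against 0.509 simulated, and at 10.7 and 31.8 mg/kg it was 0.437, against 0.518.

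**Figure D3:**
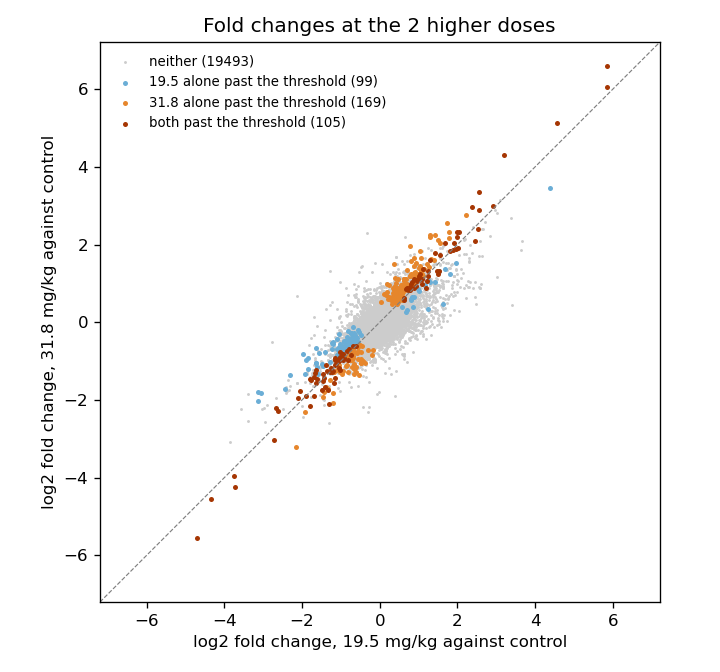
Log2 fold change against control at 19.5 mg/kg (horizontal axis) and 31.8 mg/kg (vertical axis), one point per probe, marked by the doses at which the probe was called. The 105 probes called at both doses lie in the quadrants of equal sign.

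Each fish was also placed on a scale from 0 (control mean) to 1 (31.8 mg/kg mean) over the probes called between these groups. For control and 31.8 mg/kg fish, probes and means were taken without the fish's own tank. Fish of the other doses were given the mean over 3 fits, each without 1 control tank and with all 31.8 mg/kg tanks. The 31.8 mg/kg fish were thus placed by other fits than the rest, so their positions are not on quite the same scale. This score was devised after the data had been seen. Because the own tank of control and 31.8 mg/kg fish is left out, their group means need not be 0 and 1. Control fish lay at 0.19 ± 0.09 (SD, n = 8), 7.1 mg/kg fish at 0.24 ± 0.08 (n = 7), 10.7 mg/kg fish at 0.30 ± 0.26 (n = 7), 19.5 mg/kg fish at 0.84 ± 0.26 (n = 8) and 31.8 mg/kg fish at 0.85 ± 0.25 (n = 9). The 19.5 mg/kg fish lay above control by 0.66 (two-sided exact permutation p = 0.000155, adjusted over 5 comparisons 0.000775), with 8 of 8 fish above every control fish, and above the 10.7 mg/kg fish by 0.54 (exact p = 0.00342, adjusted 0.00855). By scan date these differences were 0.87, 0.87 and 0.42, and 0.92, 0.81 and 0.20. The difference from control was 0.05 at 7.1 mg/kg (exact p = 0.258, adjusted 0.322) and 0.12 at 10.7 mg/kg (exact p = 0.257, adjusted 0.322), and between these doses it was 0.07 (exact p = 0.589). By scan date, in the same order, they were 0.10, 0.20 and -0.09, then -0.05, 0.06 and 0.22, then -0.15, -0.13 and 0.31. On tank means the exact p was 0.1 for both comparisons of the 19.5 mg/kg group, the smallest that 3 tanks against 3 allow.

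**Figure D4:**
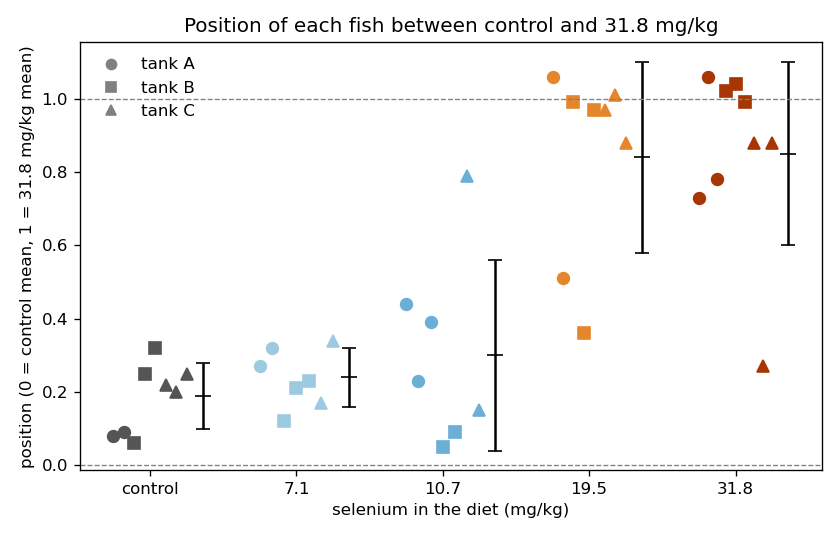
Position of each fish (vertical axis, no unit) between the control mean at 0 and the 31.8 mg/kg mean at 1, by dose group, with group mean and SD. Control fish lie between 0.06 and 0.32, and 19.5 mg/kg fish between 0.36 and 1.06.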

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

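The tests on the pair of Tank C fish and their array quality were chosen only after the fish positions had been seen, and the bound used for array quality was made one-sided after a first run that decided nothing; the position score, the array quality covariate and the pair left out were likewise added after the data had been seen.

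Against control, 204 probes were called at 19.5 mg/kg and 274 at 31.8 mg/kg, and 0 at 7.1 and 10.7 mg/kg in limma, with 774 and 483 at an unadjusted p under 0.05. Fewer fish in the lower groups are argued against, since with the higher groups reduced to 7 fish the median counts were 154.5 (8 sets, from 80 to 317) and 169 (36 sets, from 119 to 334). Array quality, as measured by the percent of spots well above background, is argued against as the whole cause. With it as a covariate, 204 and 283 probes were called. The mean log2 75th percentile was 7.92 in controls and 8.22, 8.05, 8.33 and 8.31 at 7.1, 10.7, 19.5 and 31.8 mg/kg. Whether brightness, which the scaling subtracts, still played a part in the calls was not tested. Of 100 splits of the fish, the real one included, 1 called as many probes as the real 203 at 19.5 mg/kg (highest other 11) and 2 as many as the real 275 at 31.8 mg/kg (highest other 1133), on probes without missing values. Chance assignment of single fish is argued against for both, at a share under 0.05. It is not excluded at 31.8 mg/kg, where the split with 1133 called more than the real one and points to a structure among the samples. Splits of tanks, 3 against 3, cannot give a share under 0.1. A difference in the response to dose may remain as a hypothesis, and the difference between 19.5 and 10.7 mg/kg, tested directly, rested on 16 probes. These became 0 in limma on tank means (1835 at an unadjusted p under 0.05) and with slide as a block (1808).

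The 31.8 mg/kg fish Tank C Fish 2 lay at a position of 0.27, apart from the other fish of its group (0.73 to 1.06), and the 10.7 mg/kg fish Tank C Fish 1 lay at 0.79, where the others of its group lay between 0.05 and 0.44. By the percent of probes well above background, low quality of the 2 arrays is argued against. It was 88.0% for the 10.7 mg/kg fish and 86.6% for the 31.8 mg/kg fish, against a median of 83.3% of the other arrays. No other measure of quality was tested. The log2 75th percentile was 7.79 for the 31.8 mg/kg fish (group mean 8.31) and 8.69 for the 10.7 mg/kg fish (group mean 8.05). An exchange of the 2 fish or their arrays may be a candidate explanation, because both lay on 1 slide, while only 9.52% of the pairs of a 10.7 and a 31.8 mg/kg fish (6 of 63) shared any slide. Both were also scanned on the third date. So were the 19.5 mg/kg fish Tank A Fish 2 and Tank B Fish 2, the lowest of their group (0.51 and 0.36). The other fish of that date in these groups lay at 0.73 and 0.88 at 31.8 mg/kg, 0.44 and 0.23 at 10.7 mg/kg and 0.97 and 0.88 at 19.5 mg/kg. A part played by that date was not tested for these fish. Variation between fish of one dose stays open and was not tested. Without both Tank C fish the counts were 288 at 19.5 mg/kg, 398 at 31.8 mg/kg, 341 for 31.8 against 7.1 mg/kg and 152 for 19.5 against 10.7 mg/kg. The pair was chosen for lying apart from its groups, so a rise in the counts follows from the choice and favours no cause.

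With slide as a block, the count at 19.5 mg/kg against control went from 204 to 65, of which 61 were among the 204. Differences between slides as the source of the calls are argued against, since the median ratio of the blocked to the unblocked fold change was 0.958 (quartiles 0.908 and 0.995), and the median size of change went from 1.13 to 1.06 log2 units with a median standard error 1.05 times as large. The loss could come from fewer residual degrees of freedom, since 31 of 100 shuffled slide assignments left as few calls as the real slides. The real slides left 64 on complete probes (shuffles from 27 to 261, median 92.5). Shuffling also alters the fitted fold changes, so the degrees of freedom were not tested apart from them. Between arrays of different groups, the median correlation of deviations was 0.0812 on the same slide and -0.014 on different slides.

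A fish apart from the rest of its group was found in 5 of 35 groups of values tested, where about 1.8 would be found by chance. These tests are not independent. The control fish Tank B Fish 3 was flagged for both CUST_6482_PI425320672 and CUST_2920_PI425320672. The 31.8 mg/kg fish Tank C Fish 2 was flagged for CUST_6482_PI425320672 and for its position, a score over called probes. The named probes were also chosen on these arrays, so the counts do not show an excess over chance. CUST_6482_PI425320672 lay at -1.05 in the control fish Tank B Fish 3 (other controls -7.10 to -5.20) and at -3.37 in the 31.8 mg/kg fish Tank C Fish 2 (others 0.60 to 2.78). CUST_2920_PI425320672 lay at -1.58 in the control fish Tank B Fish 3 (other controls -7.24 to -6.23). Without this control fish the differences at 31.8 mg/kg were 7.26 and 6.68 log2 units, and its position was 0.40 over rising and 0.17 over falling probes. A label exchange and mixed RNA were also tested for this fish after its values had been seen. Its position over falling probes, near the control mean of 0.19, argues only against an exchange with most 19.5 or 31.8 mg/kg fish. Their mean positions over falling probes were 0.89 and 0.84, but the 31.8 mg/kg fish Tank C Fish 2 lay at 0.21. An exchange with a 7.1 or 10.7 mg/kg fish cannot be judged from it, since the means there were 0.23 and 0.33. Mixed RNA was left undecided, and neither explanation was taken further. The percent of probes well above background was 57.5 in the 7.1 mg/kg fish Tank A Fish 3 (others 79.0 to 94.1).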

How the results depend on the processing

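The settings with scan date as a block, array quality as a covariate, single fish left out or a pair of fish left out, and all settings of the comparisons between neighbouring doses, were chosen only after the data had been seen. Counts are in the order 19.5 against control (204), 31.8 against control (274), 31.8 against 7.1 (162), 19.5 against 10.7 mg/kg (16), F test (356) and trend (706). Tank means gave 46, 60, 84, 0, 97 and 238, and slide as a block gave 65, 199, 120, 0, 200 and 432. The 0 counts in limma stood beside 1835 and 1808 probes at an unadjusted p under 0.05. Median scaling gave 100, 141, 79, 11, 210 and 539, and scan date as a block 145, 180, 97, 10, 245 and 561. Probes well above background on all 39 arrays gave 370, 319, 212, 33, 469 and 786, and the authors' values 240, 346, 195, 27, 425 and 836. The first 4 counts with the arrays of the 2 groups alone were 105, 241, 120 and 3, and array quality as a covariate gave 8 for 19.5 against 10.7 mg/kg. Without the 10.7 mg/kg fish Tank C Fish 1 and the 31.8 mg/kg fish Tank C Fish 2, chosen for lying apart from their groups, the counts for 31.8 against 7.1 and 19.5 against 10.7 mg/kg were 341 and 152. The trend over log2 mg/kg of the dosed fish gave 363. With normexp and quantile normalization, 31.8 against 19.5 mg/kg gave 1. In these settings with no sample left out, 7.1 and 10.7 mg/kg against control and 10.7 against 7.1 mg/kg stayed at 0 in limma (774, 483 and 646 at an unadjusted p under 0.05). The cause of these shifts was not tested except for slide.

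Leaving out each tank gave 23 to 310, 100 to 313, 23 to 333, 0 to 89, 168 to 432 and 460 to 808, and leaving out each fish 81 to 316, 175 to 349, 73 to 299, 0 to 87, 258 to 461 and 547 to 919. For 10.7 against 7.1 and 31.8 against 19.5 mg/kg the tanks gave 0 to 1, and for 7.1 mg/kg against control the fish gave 0 to 1. The 4 named probes at 31.8 mg/kg stayed past the threshold in each setting that tested them. CUST_6482_PI425320672 ranged from 1.98 to 7.32 log2 units and CUST_14405_PI425320672 from -6.45 to -1.31. A filter on all 39 arrays left 3 of the 4 untested.

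The tank letters are shared between groups but pair nothing. Over 30 pairs of tanks of one letter the median correlation of deviations was -0.00103 (-0.218 to 0.295, 10 above 0.1), and 4 of 15 tanks were closest to their own letter. With the letter as a block the counts were 221, 247, 133, 13, 344 and 674. The gene list alternatives were not run, because no probe has a gene name. Signal over background limits the rising named probes, whose control level is mostly below it, and CUST_14405_PI425320672, well above it on 3 of 9 arrays at 31.8 mg/kg and 3 of 8 at 19.5 mg/kg.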

Other observations

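The tests of coupling and spread between fish were chosen only after the data had been seen, as were the comparisons of neighbouring doses.

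Within a dose group, the position of a fish over rising probes was set against its position over falling probes, as 5 correlations. At 31.8 mg/kg Pearson's r was 0.904 (exact permutation p = 0.00467, adjusted 0.0154, n = 9), Spearman's rho was 0.733 (exact p = 0.0311), and r was 0.633 without the 2 fish farthest from the median. At 10.7 mg/kg r was 0.924 (exact p = 0.00615, adjusted 0.0154, n = 7), rho was 0.857 (exact p = 0.0238), and r was 0.900 without 2 fish. At 19.5 mg/kg r was 0.795 (exact p = 0.031, adjusted 0.0517, n = 8), rho was 0.548 (exact p = 0.171), and r was -0.364 without 2 fish, so the relation rests on those fish. In controls r was 0.236 (exact p = 0.566, n = 8) and at 7.1 mg/kg 0.406 (exact p = 0.385, n = 7). These correlations were not recomputed within scan dates, which hold at most 4 arrays of a group. The permutations here and for the deviations below treated fish as exchangeable and took no account of tanks. In controls and at 31.8 mg/kg, the fish of a tank were also placed by a fit of their own. The mean absolute deviation of the positions was 0.188 at 10.7 mg/kg against 0.075 in controls (exact p = 0.0673, adjusted over 4 comparisons 0.269), 0.164 at 19.5 mg/kg (exact p = 0.415, adjusted 0.553), 0.162 at 31.8 mg/kg (exact p = 0.202, adjusted 0.404) and 0.06 at 7.1 mg/kg (exact p = 0.592), so no dose passed.

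Of 100 splits of the samples into groups of the same sizes, the real one included in each count, 2 called as many probes as the real 169 for 31.8 against 7.1 mg/kg (highest other 1164), 1 as many as the real 723 for the trend (highest other 4) and 1 as many as the real 359 for the F test (highest other 5), on probes without missing values. Chance assignment of single fish is argued against for these, at a share under 0.05, which says nothing of tanks. It is not excluded for 31.8 against 7.1 mg/kg, where the split with 1164 called more than the real one. For 19.5 against 10.7 mg/kg, 2 of 100 splits called as many as the real 16, the real one and 1 other, which called 6.69 times the real count. These 16 calls are not taken as secure, since on tank means limma called 0 (1835 at an unadjusted p under 0.05). For 7.1 and 10.7 mg/kg against control, 10.7 against 7.1 and 31.8 against 19.5 mg/kg the real count was 0 in limma (774, 483, 646 and 805 at an unadjusted p under 0.05), 100 of 100 splits called as many, which a real count of 0 fixes in advance and which says nothing of chance, and the highest others were 1, 1159, 2 and 3. The splits with 1159, 1133 and 1164 calls point to a structure among the samples. The first parted arrays of a mean log2 75th percentile of 8.33 and 7.67, with 0, 3 and 4 arrays of the 3 scan dates against 3, 3 and 2. The second parted arrays with 79.8 and 86.0% of probes well above background, and the third with 79.8 and 87.7%. The split of 10.7 and 7.1 mg/kg fish with 2 calls had mean 75th percentiles of 7.92 and 8.34. That contrast was smaller than with 1159 calls. It was larger than with 1133 calls (8.14 and 8.11) or 1164 calls (8.3 and 8.23). The percent well above background in the split with 2 calls was 79.6 and 84.3%. That contrast was smaller than with 1133 or 1164 calls, but larger than with 1159 calls (82.1 and 80.8%). The arrays of the split with 2 calls were no less uneven over the 3 scan dates, with 3, 3 and 1 against 0, 2 and 5. What sets the splits with 1159, 1133 and 1164 calls apart was therefore not determined. With array quality as a covariate the real counts were 283 at 31.8 mg/kg and 146 for 31.8 against 7.1 mg/kg.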
